A study of Mus musculus with 19 samples.

How the data were processed

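Liver RNA was measured by sequencing in 19 libraries. Per the labels' protocols, tissue was lysed in Trizol, RNA was purified on columns, cytoplasmic and mitochondrial ribosomal RNA was removed by hybridization, and stranded total RNA libraries were made. Per the submitters' processing notes, cutadapt 1.16, STAR 2.7.9a and featureCounts 1.6.3 were used with the mouse build GRCm39. The role and settings of each tool, including whether reads were counted by strand, are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical gene copies could therefore be divided or merged in a way that cannot be checked, and such genes are treated as uncertain.

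The authors deposited 2 tables of raw counts per Ensembl gene, 1 for each experiment, with whole numbers and a different total in each library. In the chow experiment 55487 genes are listed and in the GAN experiment 56941, and 52257 identifiers are in both. No other column of per-sample values was present. The reference used here was GENCODE release M21 on the older build GRCm38. It served only for gene symbols, gene class, chromosome, distance between genes, and transcript length and GC content, and no coordinates from it are printed. A symbol was found for 55141 genes of the chow table and 51948 of the GAN table. Genes without a symbol held a median of 0.0402% of the counts in chow libraries and 2.00% in GAN libraries. The names of the 2 deposited tables also carry different version numbers. The 2 tables were therefore probably counted with different annotation versions, which enters every comparison between the experiments.

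Groups came from the genotype and treatment labels. The labels give no replicate numbers that pair livers, no sex and no batch within an experiment. Replicate numbers follow the order of deposit and only name a library. The labels do not state that each library is a separate animal, so p-values measure the spread between these samples.

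The chow libraries held 17879597 to 24861410 counts and the GAN libraries 14511423 to 18857589 (median 16219720). A single count equals 0.0402 to 0.0559 CPM (counts relative to the library total) in chow libraries and 0.0530 to 0.0689 CPM in GAN libraries. The limit that a count of 0 allows, 3 counts, equals 0.121 to 0.168 CPM and 0.159 to 0.207 CPM. These floors cover counting error only, since PCR copies were not separated by molecular identifiers. Libraries of the same group all differed beyond sampling noise, with a lowest chi-square per gene of 15.4 between 2 libraries, so each was used as its own replicate.

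Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were removed by filterByExpr on the groups, dispersions were estimated robustly, and glmQLFit and glmQLFTest gave quasi-likelihood p-values. These were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05 with no fold threshold. KO was tested against WT within each experiment. The difference between the 2 genotype effects, and GAN_WT against chow_WT, were contrasts in a fit of 4 group means over all 19 libraries and the shared identifiers. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD over the libraries of a group.

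Gene lists were fixed before the data were examined. They comprise 22 lists of liver pathways, 15 of cell type markers and 8 of covariates such as sex and time of day, with 1018 entries, of which 4 had no identifier in the chow table and 8 had none in the GAN table. Each list with at least 3 tested members was compared with the other genes by camera (limma 3.58.1) on voom log2 values with a preset correlation of 0.01 between genes. Camera with a correlation estimated from the data, and fry, which asks whether a list's own genes move 1 way, were run beside it. List p-values were adjusted over the lists of a comparison. Calls among a list's members are given over all genes tested and adjusted over the list alone. In bulk tissue a marker list gives the level of its transcripts and not a number of cells. The level of a list in a library is the mean over members of log2 CPM (prior count 1) minus each member's mean over the libraries.

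The genes named in the text follow a rule also fixed before the data were examined. For the 2 KO contrasts it takes Efhd1, the 6 called genes with the smallest p in each direction at a mean of at least 1 CPM, and up to 3 called members of each list with the smallest p. Predicted genes are counted but are not among the 6. Where a list has no called member, up to 2 members with the highest mean expression may be given with values. For the difference between the genotype effects it takes the 5 called genes with the smallest p in each direction, and for GAN_WT against chow_WT up to 3 called members per list. Any other gene is said to have been chosen after its values were seen.

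The procedure was tested on counts simulated from the real means and library sizes with 200 genes changed, 100 of them 2-fold and 100 of them 4-fold. In the chow comparison 62% of the 2-fold and 85% of the 4-fold changes were called, and 3.92% of the calls were unchanged genes. In the GAN comparison these shares were 81%, 98% and 4.28%. For the difference between the genotype effects they were 36%, 87% and 8.21%, and for GAN_WT against chow_WT 66%, 92% and 1.86%. Camera called the list of changed genes each time and 0 of 44 unchanged random lists. All genes of that changed list were raised 2-fold, more than the median of any list called in the 2 KO contrasts. The check therefore does not show how often camera finds shifts as small as those. Genes were simulated independently of each other, so this does not check camera on lists whose genes vary together. In the real livers, relabeled groups gave a median of 14 called lists in chow, 17 in GAN and 15 for the difference between the genotype effects.

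Alternatives set before the data were examined were DESeq2's size factors and upper-quartile factors in edgeR, no filter, a stricter filter, DESeq2 1.42.0, limma-voom with sample quality weights, an adjusted p under 0.1, library sizes without mitochondrial and the 20 most abundant genes, 1 surrogate variable (sva 3.50.0), the fit over all 19 libraries, and leaving out each library in turn. After the data were seen, male livers alone (with each of them left out in turn for 6 lists), a sex term, a pair of libraries low in Malat1 left out, and a correction for transcript length (in GAN lists, and for the length trend itself, with each library left out) were added. The length correction subtracted from each library a lowess trend (span 0.3) of log2 CPM, relative to each gene's mean, on the log2 length of the gene's longest transcript.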

Results

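Gene expression was measured in 19 mouse livers by RNA sequencing after removal of ribosomal RNA. The livers came from C57BL/6 mice lacking Efhd1 in the whole body (KO) and from wild-type mice (WT). Efhd1 encodes a calcium-binding protein of mitochondria, and the series concerns its part in metabolic liver injury through calcium-dependent division of mitochondria. In 1 experiment the mice ate chow (chow_KO n = 5, chow_WT n = 5). In a separate experiment, months apart, they ate the Gubra Amylin NASH (GAN) diet, which is rich in fat, fructose and cholesterol and is used to produce steatohepatitis (GAN_KO n = 5, GAN_WT n = 4). Diets were given for 28 weeks from 8 weeks of age. Total counts were 17879597 to 24861410 per chow library and 14511423 to 18857589 per GAN library.

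The labels give no sex, so the X-inactivation transcript Xist and the Y-linked gene Ddx3y were compared in every library. Xist measured 281 to 1460 CPM in chow_KO 1, chow_WT 2 and chow_WT 3, where Ddx3y had no counts, against a floor of 0.121 to 0.158 CPM in those libraries. In the other 16 libraries Xist was at most 4.53 CPM. Ddx3y measured 30.4 CPM in chow_KO 3 and 73.4 to 127 CPM in the other 15. The chow groups therefore differed in sex, with 1 female liver of 5 in chow_KO and 2 of 5 in chow_WT, and the 9 GAN livers were male by this measure.

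**Figure D1:**
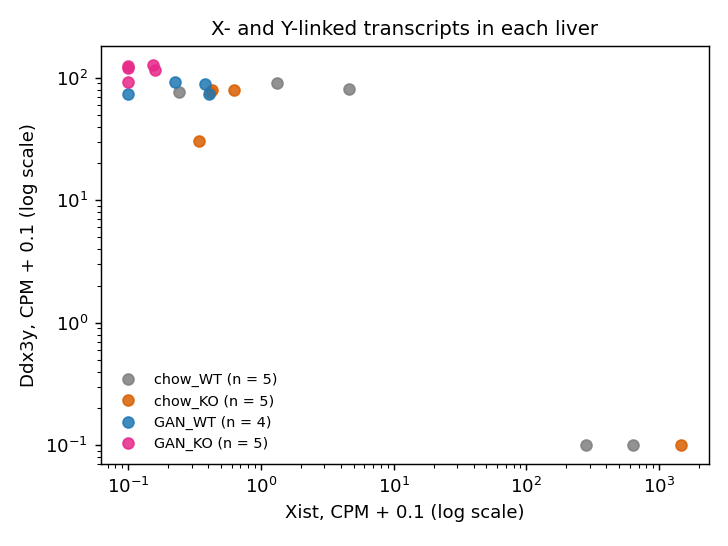
Xist (x axis) and Ddx3y (y axis) in CPM + 0.1, both on log scales, with 1 point for each of the 19 livers coloured by group. The 3 livers at the lower right, chow_KO 1, chow_WT 2 and chow_WT 3, have Xist of 281 to 1460 CPM and no Ddx3y counts.

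Efhd1 was near the detection limit in every group, so its counts could not check the genotype labels. The 5 chow_KO libraries held 0 to 7 Efhd1 counts each (0.163 ± 0.137 CPM, mean ± SD, 17 counts in all) and the 5 chow_WT libraries 0 to 8 (0.143 ± 0.118 CPM, 16 counts). The 5 GAN_KO libraries held 1 or 2 counts (0.106 ± 0.0251 CPM, 9 counts) and the 4 GAN_WT libraries 0 to 6 (0.197 ± 0.155 CPM, 13 counts). A single count is worth 0.0402 to 0.0689 CPM, and the gene was removed by the filter on low counts in both experiments. A difference in Efhd1 was not detectable at this depth, and the deleted part of the gene is not stated in the sources used here. The genotype of each library is therefore taken from its label.

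The chow experiment asks what loss of Efhd1 does to the liver on a standard diet. By edgeR no gene separated KO from WT livers beyond the spread between livers, and DESeq2 called 2. As groups, genes of antigen presentation, the interferon response, the acute phase, the cell cycle and bile duct cells lay lower in KO livers, with list medians from -0.14 to -0.43 on the log2 scale. Genes of protein folding in the endoplasmic reticulum (ER), fatty acid oxidation and pericentral metabolism lay higher, with list medians of 0.10 to 0.12. None of these groups stood out with a correlation estimated from the data, and 5 of the lists called changed the sign of their median in male livers alone. The higher level of ER genes rested on chow_KO 3 (median 0.01 without it). Of the 17 lists called, 2 (interferon and acute phase) were called with each library left out in turn. A median as large in size came from 37 of 100 splits of the chow libraries for interferon, the real one included. For the acute phase it came from 30 of 100, so chance could not be excluded for either.

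Of 14675 genes tested by edgeR, 0 were higher and 0 lower in chow_KO (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 63 genes higher and 117 lower, 1.23% of those tested, and DESeq2 called 1 gene higher and 1 lower. The median SE of a log2 fold change was 0.191. The gene called lower by DESeq2 was Col1a1, which encodes the main collagen chain of scar tissue and was chosen after its values were seen. Col1a1 measured 8.25 ± 1.68 CPM in the 5 KO livers and 16.5 ± 3.58 CPM in the 5 WT livers, with every KO liver below every WT liver (log2 fold change -0.998 with SE 0.18, edgeR adjusted p = 1.00, DESeq2 adjusted p = 0.0182). Another fibrillar collagen chosen in that way, Col3a1, measured 49.0 ± 5.95 and 65.6 ± 10.5 CPM.

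Antigen presentation genes were below WT in all 18 members tested (median -0.15, camera adjusted p = 0.00184), with 0 members called adjusted over the list alone. Interferon-stimulated genes were below WT in 30 of 33 members (median -0.14, camera adjusted p = 1.12e-05). They include the GTPase Iigp1, at 443 ± 98.8 CPM in KO and 481 ± 73.6 CPM in WT, and Bst2, which tethers budding virus, at 69.5 ± 8.45 and 81.7 ± 20.8 CPM. Acute phase genes were below WT in 24 of 26 members (median -0.22, camera adjusted p = 2.50e-05). The fibrinogen chains Fga (5751 ± 1109 and 6449 ± 1692 CPM) and Fgb (5098 ± 1118 and 5764 ± 1295 CPM) overlapped between the groups. Cell cycle genes were below WT in 24 of 30 members (median -0.33, camera adjusted p = 0.00303) and replication histones in 10 of 11 (median -0.22, camera adjusted p = 0.0268). The camera adjusted p with an estimated correlation was 0.645 to 0.726 for these 5 lists. Antigen presentation was not called without chow_KO 5 (median -0.11), chow_WT 2 (-0.08) or chow_WT 3 (-0.02, 9 of 18 members below WT), and its median was -0.23 without chow_WT 1. The cell cycle list was not called without chow_KO 2 (-0.19), chow_KO 3 (-0.19), chow_WT 2 (-0.05) or chow_WT 3 (-0.18), nor histones without chow_KO 1 (-0.20), chow_KO 5 (-0.27), chow_WT 2 (-0.10) or chow_WT 3 (-0.18), nor after the correction for transcript length (-0.16, camera adjusted p = 0.0808). The interferon median was -0.23 without chow_KO 2, -0.34 without chow_KO 4 and -0.22 without chow_WT 1.

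Bile duct markers were below WT in 9 of 10 members (median -0.43, camera adjusted p = 0.0116), among them the cilium protein Pkhd1 at 17.3 ± 7.15 and 20.7 ± 6.02 CPM and osteopontin, Spp1, at 19.6 ± 4.88 and 27.1 ± 17.0 CPM. Markers of lipid-associated macrophages were below WT in 9 of 11 (median -0.29, camera adjusted p = 0.0303), among them the fatty acid binding protein Fabp5 (67.5 ± 30.0 and 114 ± 84.5 CPM) and the fatty acid transporter Cd36 (43.7 ± 6.55 and 51.2 ± 12.9 CPM). Matrix and fibrosis genes were below WT in 26 of 37 (median -0.12, camera adjusted p = 0.0268), with 1 lower adjusted over the list alone. The 2 most abundant of them, Fn1 (3289.5 ± 471 and 2911 ± 460 CPM) and Dcn (119 ± 13.4 and 132 ± 29.9 CPM), lay on opposite sides. In camera with an estimated correlation, the adjusted p was 0.645 for each of these 3 lists. Bile duct markers were not called without chow_KO 3 (median -0.30), chow_KO 5 (-0.47), chow_WT 1 (-0.40), chow_WT 4 (-0.26) or chow_WT 5 (-0.24). Lipid-associated macrophages were not called without chow_KO 1 (-0.30), chow_KO 5 (-0.31), chow_WT 3 (-0.20) or chow_WT 4 (-0.26). Matrix genes were not called without chow_KO 4 (-0.10), chow_KO 5 (-0.11), chow_WT 2 (-0.07), chow_WT 3 (-0.06) or chow_WT 4 (-0.08).

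ER stress and folding genes were above WT in 19 of 22 members (median 0.12, camera adjusted p = 9.93e-05), as in the chaperones Calr (869 ± 246 and 809 ± 38.1 CPM) and Hsp90b1 (830 ± 87.1 and 794 ± 65.5 CPM). This rested on chow_KO 3, with a list level of 0.57 against -0.16 to 0.02 in the other KO livers. That library also had the fewest genes with a count of the 10 (19653), 28.2% of its counts on its 20 most abundant genes (at most 24.5% in the other KO libraries), and low nuclear Malat1 (892 CPM, other KO libraries 2545 to 6675, but 874 in chow_WT 3) and Y-linked Eif2s3y (1.75 CPM, other male KO livers 39.0 to 50.1). Without it 12 of 22 members were above WT (median 0.01, camera adjusted p = 0.532) and the log2 fold change of Calr was -0.09. Genes of the integrated stress response and mitochondrial protein folding were above WT in 17 of 22 (median 0.12, camera adjusted p = 0.0398), as in Hspa9 (396 ± 29.2 and 346 ± 22.4 CPM) and Hspd1 (322 ± 50.9 and 311 ± 29.5 CPM). Without chow_KO 3 this list had 11 of 23 members above WT (median -0.0041, camera adjusted p = 0.828), and it was not called either without chow_KO 2 (0.10), chow_KO 4 (0.13), chow_WT 3 (0.16), chow_WT 4 (0.05) or chow_WT 5 (0.07). Fatty acid oxidation genes were above WT in 28 of 40 (median 0.10, mean 0.01, camera adjusted p = 0.00148), including Acox1 (2182 ± 582 and 1868 ± 374 CPM) and Hmgcs2 (2153 ± 526 and 2042 ± 290 CPM). Pericentral genes were above WT in 14 of 20 (median 0.10, camera adjusted p = 0.0423), including Cyp2e1 (5679 ± 1098 and 4956 ± 1317 CPM). Mitophagy genes (18 of 24, median 0.06, camera adjusted p = 0.0268), mitochondrial calcium genes (19 of 31, median 0.04, camera adjusted p = 0.0303) and drug metabolism genes (16 of 25, median 0.06 but mean -0.03, camera adjusted p = 0.0268) were also above WT by this test. With an estimated correlation the camera adjusted p of these 7 lists was 0.645 to 0.726. Fatty acid oxidation was not called without chow_KO 5 (median 0.0026) or chow_WT 4 (0.01), and its median was 0.16 without chow_WT 2. Pericentral genes were not called without chow_KO 3 (0.09), chow_KO 4 (0.08), chow_KO 5 (0.10), chow_WT 1 (0.09) or chow_WT 4 (0.06), and their median was 0.16 without chow_KO 2 or chow_WT 2 and 0.17 without chow_WT 3. Mitophagy genes were not called without chow_KO 3 (0.02), chow_KO 5 (0.05), chow_WT 2 (0.03) or chow_WT 4 (0.06), and their median was 0.10 without chow_KO 1. Mitochondrial calcium genes were not called without chow_KO 3, chow_KO 5, chow_WT 1, chow_WT 2, chow_WT 4 or chow_WT 5, and over all 10 libraries left out their median ran from 0.0095 to 0.07. Drug metabolism genes were not called without chow_KO 1, chow_KO 3, chow_KO 4, chow_KO 5, chow_WT 1 or chow_WT 4, and over all 10 their median ran from -0.10 (without chow_WT 4) to 0.25 (without chow_WT 3). The machinery of mitochondrial fission and fusion was divided, with 14 members above and 13 below WT (median 0.01, camera adjusted p = 0.286).

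Sex moved with genotype in these lists. Male-biased liver genes were above WT in 16 of 16 members (median 0.39, camera adjusted p = 0.00140, and 0.725 with an estimated correlation), and female-biased genes were below WT in 11 of 11 (median -1.16, camera adjusted p = 0.157). Clock genes were above WT in 15 of 20 (median 0.30, camera adjusted p = 0.0268, and 0.645 with an estimated correlation). Male-biased genes were not called without chow_KO 3 (median 0.32), chow_WT 2 (0.15) or chow_WT 3 (0.21), and had a median of 0.24 without chow_KO 5 and of 0.66 without chow_KO 1. Clock genes were not called without chow_KO 1 (0.25), chow_KO 3 (0.25), chow_KO 5 (0.09), chow_WT 2 (0.25), chow_WT 3 (0.28) or chow_WT 4 (0.23), nor after the length correction (0.28, camera adjusted p = 0.0603). In the 7 male livers alone, an alternative chosen after the data were seen, 5 medians of the lists called above turned positive. These were antigen presentation (0.19), the cell cycle (0.11), replication histones (0.18), matrix genes (0.05) and lipid-associated macrophages (0.03), none of them called there, while bile duct markers stayed negative in 10 of 11 members (median -0.65, camera adjusted p = 0.00165, and 0.609 with an estimated correlation). Their median in male livers was -0.36 without chow_KO 3 and -0.41 without chow_WT 5. Interferon genes (median -0.04, camera adjusted p = 0.181) were not called in male livers.

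The GAN experiment asks what loss of Efhd1 does to the liver under a diet that injures it. Many genes tended apart between GAN_KO and GAN_WT livers, but none passed the adjusted threshold in edgeR, whereas DESeq2 called 112 higher and 35 lower. Transcripts of macrophages, T and NK cells and neutrophils, cytokine genes and genes of protein folding in the ER lay lower in KO livers. Transcripts of the liver endothelium lay higher, by a list median of 0.26 on the log2 scale, in 14 of 17 markers. Without 1 wild-type liver, GAN_WT 1, the median of macrophage transcripts was -0.36 instead of -0.71 and that of T and NK cell transcripts -0.33 instead of -0.87. None of these groups stood out with a correlation estimated from the data.

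Of 14261 genes tested by edgeR, 0 were higher and 0 lower (smallest adjusted p = 0.0598). At an unadjusted p under 0.05 there were 1300 genes higher and 841 lower, 15.0% of those tested. DESeq2 called 112 higher and 35 lower, and edgeR without a filter 41 higher and 5 lower. The smallest adjusted p belonged to Gm47283, a predicted gene of the Y chromosome chosen after its values were seen, with 12 to 24 counts in every GAN_KO library and 0 in all 4 GAN_WT libraries (1.07 ± 0.275 CPM in KO, against a floor of 0.168 to 0.207 CPM in WT). In the chow experiment it measured 5.38 CPM in chow_KO 1 and 2.65 CPM in chow_WT 3, both female by Xist and Ddx3y. These values argue against an origin of its chow reads on the Y chromosome alone. Its reads may belong to near-identical sequence elsewhere, and the gene is reported as uncertain. Next came Ifitm1, an interferon-induced membrane protein chosen in that way, at 4.59 ± 0.198 CPM in KO and 7.74 ± 0.573 CPM in WT, with every KO liver below every WT liver (log2 fold change -0.75 ± 0.12 SE, edgeR adjusted p = 0.238).

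Macrophage markers were below WT in 15 of 18 members (median -0.71, camera adjusted p = 4.32e-05), and 10 were lower adjusted over the list alone. Lysozyme, Lyz2, measured 240 ± 47.7 CPM in KO and 549 ± 420 CPM in WT (log2 fold change -1.19 ± 0.39 SE, edgeR adjusted p = 0.252), and the macrophage survival factor Cd5l 381 ± 59.6 and 615 ± 299 CPM. T and NK cell markers were below WT in 11 of 11 (median -0.87, camera adjusted p = 9.37e-04), with 3 lower adjusted over the list alone. The T cell receptor constant gene Trbc2 measured 1.43 ± 0.412 CPM in KO and 3.14 ± 1.33 CPM in WT, and the kinase Lck 0.930 ± 0.208 and 1.63 ± 1.34 CPM. Neutrophil markers were below WT in 8 of 8 (median -0.64, camera adjusted p = 0.0167), among them S100a8 (3.71 ± 1.51 and 7.96 ± 5.40 CPM) and S100a9 (3.70 ± 1.25 and 7.78 ± 4.65 CPM). Lipid-associated macrophage markers were below WT in 13 of 14 (median -0.37, camera adjusted p = 0.0218), although the most abundant, Cd36, was above it (430 ± 50.6 and 365 ± 25.6 CPM). They were not called without GAN_KO 1 (median -0.28), GAN_KO 2 (-0.30), GAN_WT 1 (-0.15) or GAN_WT 3 (-0.31), with a median of -0.59 without GAN_WT 4, nor were neutrophil markers without GAN_KO 2 (-0.48) or GAN_WT 1 (-0.33). The camera adjusted p with an estimated correlation was 0.837 for each of these 4 lists.

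Cytokine and chemokine genes were below WT in 34 of 36 members (median -0.25, camera adjusted p = 3.37e-04), as in the receptor Csf1r (101 ± 13.7 and 140 ± 64.6 CPM) and the chemokine Ccl9 (59.8 ± 8.90 and 64.9 ± 15.3 CPM). Antigen presentation genes were below WT in 15 of 18 (median -0.26, camera adjusted p = 0.00103), as in B2m (2345 ± 180 and 2715 ± 260 CPM) and H2-K1 (927 ± 116 and 1044 ± 51.8 CPM). Acute phase genes were below WT in 22 of 26 (median -0.14, camera adjusted p = 0.0233), as in the heme carrier Hpx (4624 ± 404 and 5914 ± 516 CPM) and haptoglobin, Hp (3243 ± 134 and 3759.6 ± 510 CPM). Interferon genes went the other way, above WT in 22 of 33 (median 0.11, camera adjusted p = 0.0369), with Iigp1 at 422 ± 39.9 and 362 ± 90.7 CPM and Bst2, on the other side, at a log2 fold change of -0.17 ± 0.13 SE. Without GAN_WT 1 the interferon list was above WT in 31 of 33 (median 0.31, camera adjusted p = 3.55e-07), with 5 higher adjusted over the list alone, and it was not called without GAN_WT 2 (median 0.09), GAN_WT 3 (0.0072), GAN_WT 4 (0.10), GAN_KO 3 (0.10) or GAN_KO 5 (0.04). The acute phase list was not called without GAN_KO 2 (-0.08), GAN_WT 3 (-0.06) or GAN_WT 4 (-0.09). In camera with an estimated correlation, the adjusted p was 0.837 for each of these 4 lists. Of the B cell markers, 8 of 11 were below WT (median -0.54, camera adjusted p = 0.134).

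A single liver, GAN_WT 1, stood well above the rest in the immune lists, with a macrophage level of 1.28 and a T and NK cell level of 1.35 on the log2 scale against at most 0.30 in the other 8 livers. Without it the macrophage median was -0.36 (camera adjusted p = 6.82e-04) and the T and NK cell median -0.33 (camera adjusted p = 0.0375), with 0 members called adjusted over either list alone. Without it the cytokine (median -0.04, camera adjusted p = 0.377), neutrophil (median -0.33, camera adjusted p = 0.232) and lipid-associated macrophage (median -0.15, camera adjusted p = 0.315) lists were not called, and antigen presentation had a median of -0.13 (camera adjusted p = 0.0458). The 3 lists not called with all livers but called without it were the cell cycle (28 of 30 above WT, median 0.27, camera adjusted p = 5.54e-04), matrix genes (28 of 40 above WT, median 0.17, camera adjusted p = 0.0324) and hepatocyte markers (17 of 19 below WT, median -0.17, camera adjusted p = 0.0217).

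Endothelial markers were above WT in 14 of 17 members (median 0.26, camera adjusted p = 4.32e-05, and 0.789 with an estimated correlation), and 8 were higher adjusted over the list alone. The vascular phosphatase Ptprb measured 153 ± 28.8 CPM in KO and 90.4 ± 15.9 CPM in WT, with all 5 KO livers above all 4 WT livers (log2 fold change 0.76 ± 0.16 SE, edgeR adjusted p = 0.238). The scavenger receptor Stab2, of the sinusoidal endothelium, measured 144 ± 21.2 and 113 ± 6.19 CPM (log2 fold change 0.35 ± 0.11 SE, edgeR adjusted p = 0.241). Stab1 (61.3 ± 14.5 and 39.8 ± 3.39 CPM), the VEGF receptor Kdr (78.1 ± 14.8 and 52.9 ± 6.95 CPM) and Vwf (10.3 ± 3.03 and 6.03 ± 1.23 CPM), chosen after their values were seen, were likewise higher in all 5 KO livers than in any WT liver. Without GAN_WT 1 the list median was 0.34 and 8 members were again higher adjusted over the list alone.

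**Figure D2:**
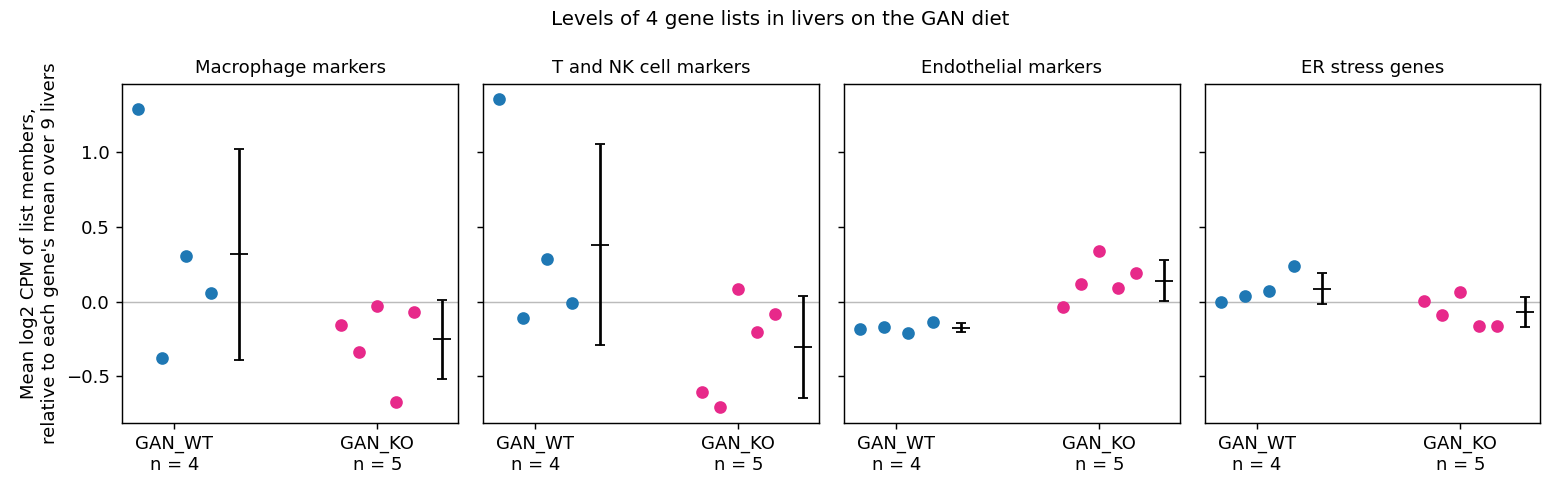
Level of 4 gene lists (y axis, mean log2 CPM of the members relative to each gene's mean over the 9 GAN livers) in GAN_WT (n = 4) and GAN_KO (n = 5). Each point is a liver, and bars give mean ± SD. GAN_WT 1 reaches 1.28 for macrophage and 1.35 for T and NK cell markers, and all 5 KO livers lie above the 4 WT livers for endothelial markers.

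ER stress and folding genes were below WT in 16 of 22 members (median -0.19, camera adjusted p = 0.0197, and 0.837 with an estimated correlation), with 2 lower adjusted over the list alone. Without GAN_WT 4 the list was not called (median -0.12, camera adjusted p = 0.141). The chaperone Calr measured 774 ± 114 and 951 ± 55.8 CPM and Hsp90b1 912 ± 76.5 and 951 ± 91.3 CPM. Among members chosen after their values were seen, Sdf2l1 measured 16.5 ± 3.55 and 26.3 ± 3.62 CPM and the disulfide isomerase Pdia6 230 ± 27.0 and 308 ± 25.1 CPM, both with every KO liver below every WT liver. Nuclear genes of the respiratory chain were below WT in 72 of 75 (median -0.14, camera adjusted p = 3.51e-06, and 0.837 with an estimated correlation), as in Atp5b (1007 ± 131 and 1119 ± 109 CPM) and Atp5a1 (916 ± 125 and 981 ± 109 CPM), and the median was -0.22 without GAN_KO 2 and -0.08 without GAN_KO 5. Mitochondrially encoded genes lay the other way in 10 of 12 (median 0.14, camera adjusted p = 0.0768) without being called. Fission and fusion genes were divided, with 13 above and 14 below WT (median -0.02, camera adjusted p = 0.939). Of the mitochondrial calcium genes 21 of 32 were above WT (median 0.06, camera adjusted p = 0.234), with 1 higher adjusted over the list alone. Male-biased liver genes were below WT in 14 of 15 although all livers were male (median -0.38, camera adjusted p = 3.37e-04, and 0.837 with an estimated correlation). The 4 tested sex chromosome genes were above WT (median 0.18, camera adjusted p = 0.0369, and 0.789 with an estimated correlation), a call that ended without GAN_KO 1 (0.19), GAN_KO 4 (0.18), GAN_WT 1 (0.15) or GAN_WT 3 (0.20), or after the length correction (0.10, camera adjusted p = 0.233).

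Fold changes in the GAN experiment followed transcript length, unevenly across livers. The slope of log2 expression per doubling of length was 0.17 in GAN_KO 5, 0.097 in GAN_KO 4 and 0.029 in GAN_KO 3, but -0.020 in GAN_KO 1 and -0.045 in GAN_KO 2, against -0.094 to -0.029 in the GAN_WT libraries. Across genes, which are not independent replicates, Spearman's rho between log2 fold change and transcript length was 0.437 in the GAN comparison (0.340 to 0.487 with 1 library left out, lowest without GAN_KO 5) and 0.179 in the chow comparison. The median log2 fold change was -0.14 in the shortest of 10 length classes of genes and 0.27 in the longest in the GAN comparison. The respiratory chain list, of short transcripts, lay at the 23.7 percentile of 10000 lists matched on length and expression and was not called after the length correction (median -0.04, camera adjusted p = 0.262). The acute phase list was not called after it either (median -0.08, camera adjusted p = 0.262), whereas the macrophage (median -0.61, camera adjusted p = 3.07e-04), ER stress (median -0.14, camera adjusted p = 0.00257) and endothelial (median 0.25, camera adjusted p = 3.15e-04) lists were. After the correction the macrophage median was -0.23 without GAN_WT 1 and the endothelial median 0.10 without GAN_KO 3, both still called, and ER stress was not called without GAN_WT 4 (median -0.08, camera adjusted p = 0.0821). The corrected T and NK cell (median -0.24, camera adjusted p = 0.162) and antigen presentation lists (median -0.06, camera adjusted p = 0.238) were called with all livers but not without GAN_WT 1. The correction also added 6 calls, all higher in KO. They were mitochondrially encoded genes (12 of 12, median 0.29, camera adjusted p = 3.07e-04), fatty acid oxidation (31 of 40, median 0.14, camera adjusted p = 0.00132), lipid droplets (median 0.10, camera adjusted p = 0.0313), the cell cycle (median 0.12, camera adjusted p = 0.0375), periportal genes (median 0.11, camera adjusted p = 0.0460) and female-biased genes (median 0.18, camera adjusted p = 0.0471). With an estimated correlation every list called after the correction had a camera adjusted p of 0.930, and fry gave 0.820 to 0.877. GAN_KO 5 stood apart in mitochondrially encoded RNA (12.4% of counts, others of its group 8.82 to 9.70%). This share includes the ribosomal RNA mt-Rnr2, at 74628 CPM in GAN_KO 5 and 45552 to 58033 CPM in the others of its group. The list level of GAN_KO 5 was 0.32 while GAN_KO 3 and GAN_KO 4 lay below 0. Without GAN_KO 5 the corrected median of the list was 0.22 (camera adjusted p = 3.31e-04). Among the 6, mitochondrially encoded genes were called with each library left out, each time after the same kind of correction. Without the correction their median was 0.14 and they were not called. Whether mitochondrial transcripts follow the length trend was not tested, so this stability may come from the correction. Fatty acid oxidation was not called without GAN_WT 1 (0.05, and 0.21 without GAN_WT 4), lipid droplets without GAN_KO 2, GAN_KO 4, GAN_KO 5, GAN_WT 1 (0.03) or GAN_WT 2, the cell cycle without GAN_KO 2, GAN_KO 3, GAN_WT 2 or GAN_WT 4 (-0.07), periportal genes without GAN_KO 1, GAN_KO 2, GAN_WT 1 (-0.04) or GAN_WT 3, and female-biased genes without GAN_KO 1, GAN_KO 2, GAN_KO 4, GAN_WT 1, GAN_WT 2 or GAN_WT 3 (-0.06).

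**Figure D3:**
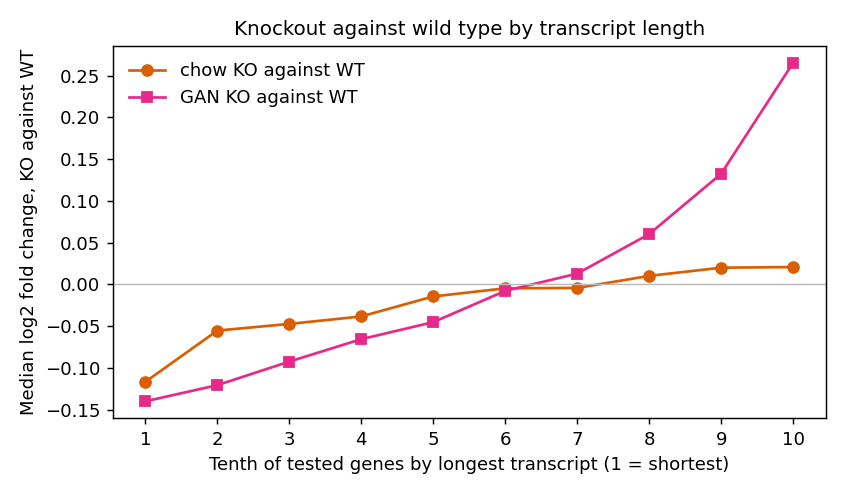
Median log2 fold change of KO against WT (y axis) for 10 classes of the tested genes, equal in size and ordered by the length of the longest transcript (x axis, 1 the shortest), in the chow and the GAN experiment. In GAN livers the medians run from -0.14 to 0.27 and in chow livers from -0.12 to 0.02.

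Whether the genotype effect differed between the experiments was tested directly in all 19 libraries. By edgeR no gene differed beyond the spread between livers, and limma-voom with quality weights called 1. Lists called by camera covered immune cells, the endothelium, matrix, mitochondria, stress responses, the cell cycle, interferon and male-biased genes. Sex enters this contrast, since the chow groups differed in sex and all GAN livers were male. In male chow livers alone, 17 list medians of KO against WT changed sign. These included macrophages (-0.15 to 0.18), the endothelium (-0.0069 to 0.14) and the respiratory chain (-0.08 to 0.23), but not ER stress (0.12 to 0.20). Of 100 relabelings, 51 called at least as many lists as the real labels. Of 15737 genes tested by edgeR, 0 had a higher and 0 a lower effect on the GAN diet (smallest adjusted p = 0.974). At an unadjusted p under 0.05 there were 500 higher and 201 lower, 4.45%, and DESeq2 called 0. Camera called 5 lists higher and 10 lower of 44. The ER stress list had a lower effect on the GAN diet in 18 of 22 members (median -0.23, camera adjusted p = 1.47e-05), with Calr at a difference in log2 fold change of -0.40 ± 0.23 SE, and a list median of -0.09 without chow_KO 3 (camera adjusted p = 0.00163). The macrophage list was lower in 15 of 18 (median -0.53, camera adjusted p = 1.58e-04), with Lyz2 at -1.15 ± 0.50 SE, and was not called without GAN_WT 1 (median -0.16, camera adjusted p = 0.123). The endothelium list was higher in 14 of 17 (median 0.31, camera adjusted p = 7.99e-05) with 4 higher adjusted over the list alone, and Ptprb at 0.81 ± 0.23 SE, and had a median of 0.16 without chow_WT 2. The interferon list was higher in 31 of 33 (median 0.31, camera adjusted p = 1.47e-05), with Iigp1 at 0.35 ± 0.25 SE, and had a median of 0.49 without GAN_WT 1 and 0.19 without GAN_WT 3. The genes named for this contrast were chosen after their values were seen. With an estimated correlation the camera adjusted p of each of these lists was 0.876.

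Fold changes of the 2 KO contrasts, which share no library, were nearly unrelated across 13277 genes (Pearson's r = 0.04, Spearman's rho = 0.11, same sign in 55.0%). With genotype labels permuted within each experiment, 75 of 99 draws gave an r as far from 0 (range -0.32 to 0.23). Genes near Efhd1, on chromosome 1, were no more frequent among those at an unadjusted p under 0.05 than among all genes tested, a set used because no gene was called. Within 20 Mb lay 2 of 180 such genes in chow livers and 25 of 2141 in GAN livers (Fisher's exact p = 1.00 for both, smallest adjusted p = 0.708 over 12 tests).

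The experiments on the 2 diets differed in most of the transcriptome. In wild-type livers, genes of inflammation, macrophages, lipid droplets and antioxidant defence were higher in the GAN experiment, and those of cholesterol synthesis, hepatocyte identity and the endothelium were lower. Gpnmb, a membrane protein of lipid-laden macrophages, measured 128 ± 72.7 CPM in the 4 GAN_WT livers and 0.260 ± 0.245 CPM in the 5 chow_WT livers, and the cholesterol synthesis enzyme Sqle was 87.1-fold lower on GAN. By edgeR 4392 genes rose and 4868 fell of 15737 tested, and 9959 had an unadjusted p under 0.05. Diet, date, count table and the mix of sexes changed together, so these are differences between experiments and cannot be assigned to the diet. In male livers alone 4820 genes were higher and 4961 lower, with 8427 of the calls kept in the same direction and 1 reversed. These values argue against the mix of sexes as the source of most of the calls. The signs of a technical difference were large. Mitochondrial ribosomal RNA, mt-Rnr2, had a median of 666 CPM in chow and 49166 CPM in GAN libraries. Mitochondrially encoded genes held 3.90% and 8.93% of counts, which is not a separate sign, since mt-Rnr2 is one of them. Blood transcripts rose in 6 of 8 and fell in 0 (median 4.07, camera adjusted p = 3.11e-04, and 0.792 with an estimated correlation), with the haemoglobin gene Hbb-bs, chosen after its values were seen, going from 3.89 ± 2.08 to 392 ± 95.6 CPM, so removal of blood or of globin RNA may have differed. The median of these transcripts was 2.43 without GAN_WT 3 and 2.46 without GAN_WT 4. Of the 13 mitochondrially encoded genes 3 rose and 6 fell (median -0.06, camera adjusted p = 0.209).

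Of 37 cytokine and chemokine genes 26 rose and 1 fell (median 1.43, camera adjusted p = 5.08e-06). The monocyte chemokine receptor Ccr2 rose from 1.63 ± 0.641 to 21.7 ± 8.66 CPM (log2 fold change 3.73 ± 0.34 SE, edgeR adjusted p = 2.70e-08) and its ligand Ccl2 from 0.596 ± 0.344 to 6.84 ± 2.61 CPM. Of 18 macrophage markers 13 rose and 1 fell (median 1.64, camera adjusted p = 4.40e-04), with Lyz2 up by 3.28 ± 0.38, Cd68 by 2.28 ± 0.24 and Cd5l by 2.16 ± 0.26 (log2 ± SE). Of 14 lipid-associated macrophage markers 13 rose and 1 fell (median 3.31, camera adjusted p = 1.39e-05), with the lipid sensor Trem2 going from 0.747 ± 0.425 to 20.4 ± 9.67 CPM and Cd36 from 52.0 ± 14.5 to 373 ± 27.0 CPM (log2 fold change 2.84 ± 0.17 SE, edgeR adjusted p = 1.16e-10). Neutrophil (7 of 10 rose, median 2.33, camera adjusted p = 0.0153) and B cell (7 of 11 rose, median 1.51, camera adjusted p = 0.0280) markers were higher, as in S100a8 (0.643 ± 0.373 to 8.08 ± 5.36 CPM) and Ighm (6.08 ± 0.958 to 37.7 ± 35.2 CPM). Antigen presentation genes rose in 9 of 18 and fell in 4 (median 0.64, camera adjusted p = 0.0413), with the class II genes H2-Ab1 and H2-Aa up by 2.91 ± 0.35 and 2.88 ± 0.35, and were not called without chow_WT 1 (median 0.54), chow_WT 4 (0.61), chow_WT 5 (0.58) or GAN_WT 1 (0.56). The camera adjusted p with an estimated correlation was 0.792 for these 6 lists, whereas fry, which tests a list's own genes, gave adjusted p of at most 0.00586.

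**Figure D4:**
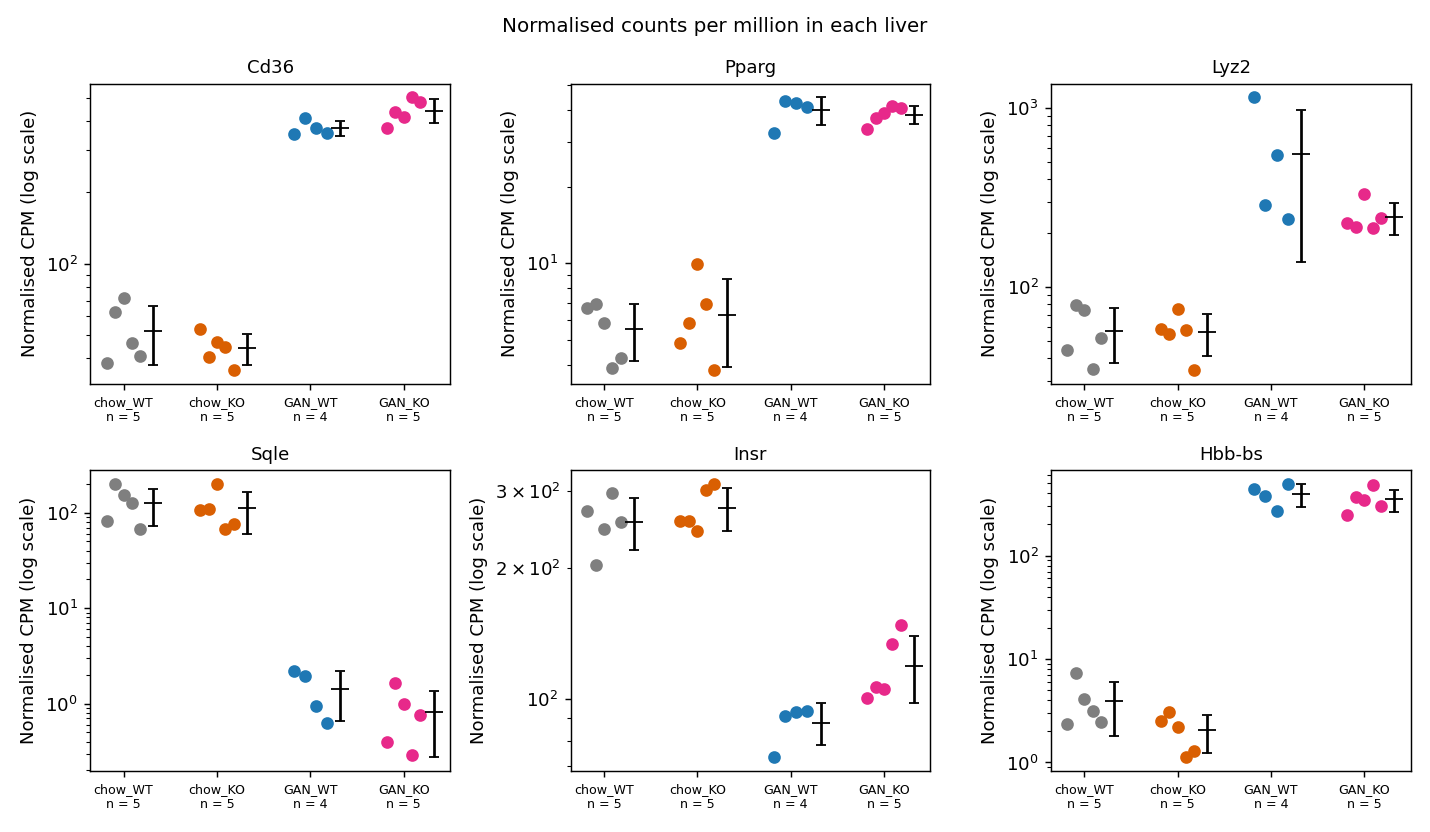
Normalised CPM (y axis, log scale) of Cd36, Pparg, Lyz2, Sqle, Insr and Hbb-bs in each liver of the 4 groups (x axis, n = 5, 5, 4 and 5 for chow_WT, chow_KO, GAN_WT and GAN_KO). Points are livers and bars give mean ± SD. Sqle averages 126 CPM in chow_WT and 1.43 CPM in GAN_WT, and Cd36 52.0 and 373 CPM.

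Matrix and fibrosis genes rose in 19 of 40 and fell in 5 (median 0.70, camera adjusted p = 0.0413). The proteoglycan Dcn rose from 134 ± 33.3 to 455 ± 97.6 CPM, the protease inhibitor Timp1 from 0.152 ± 0.185 to 4.59 ± 1.58 CPM, and fibronectin, Fn1, fell from 2942 ± 460 to 744 ± 104 CPM. The matrix list was not called without chow_KO 1 (median 0.69), chow_WT 1 (0.67), chow_WT 5 (0.71), GAN_KO 5 (0.70), GAN_WT 1 (0.67) or GAN_WT 3 (0.48). Cell cycle genes rose in 11 of 30 and fell in 0 (median 0.56, camera adjusted p = 0.00944), as in Mcm2 and Pcna, up by 1.73 ± 0.26 and 1.06 ± 0.16. Cell death genes rose in 17 of 29 and fell in 4 (median 0.51, camera adjusted p = 0.0153), with the p53 targets Gadd45a and Ccng1 up by 2.29 ± 0.27 and 1.21 ± 0.13. Endothelial markers fell in 9 of 17 and rose in 1 (median -0.45, camera adjusted p = 0.0257), with Eng, Stab1 and Ptprb at -1.69 ± 0.15, -1.42 ± 0.17 and -1.40 ± 0.17, and the list was not called without chow_WT 2 (median -0.35). In camera with an estimated correlation, the adjusted p was 0.792 for these 4 lists. Stellate cell (10 rose and 2 fell of 17), bile duct (7 rose and 2 fell of 12) and T and NK cell markers (6 rose and 0 fell of 15) were not called as lists (camera adjusted p = 0.0889, 0.465 and 0.125).

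Cholesterol synthesis genes fell in 20 of 26 and rose in 0 (median -1.59, camera adjusted p = 1.10e-06). Sqle fell from 126 ± 53.6 to 1.43 ± 0.764 CPM (log2 fold change -6.44 ± 0.53 SE, edgeR adjusted p = 2.10e-08), the sterol reductase Tm7sf2 from 143 ± 44.3 to 17.5 ± 5.21 CPM, and the regulator of the pathway, Srebf2, from 103 ± 33.7 to 14.8 ± 0.593 CPM. Lipid droplet genes rose in 15 of 24 and fell in 4 (median 1.10, camera adjusted p = 3.11e-04). The adipogenic receptor Pparg rose from 5.53 ± 1.39 to 39.8 ± 4.99 CPM, and the droplet protein Cidec, chosen after its values were seen, from 0.828 ± 0.518 to 94.7 ± 16.3 CPM. Fatty acid oxidation genes rose in 15 of 40 and fell in 2 (median 0.21, camera adjusted p = 0.0257), with Fabp1, Acaa1b and Hsd17b4 up by 2.44 ± 0.20, 2.09 ± 0.21 and 1.10 ± 0.12, and were not called without chow_WT 4 (median 0.12) or GAN_WT 4 (0.08). Antioxidant genes rose in 21 of 31 and fell in 4 (median 0.76, camera adjusted p = 1.97e-05), as in the glutathione transferases Gsta1 (0.135 ± 0.113 to 14.3 ± 4.68 CPM) and Gstm3 (32.4 ± 5.37 to 269 ± 48.4 CPM) and the lipid peroxidase Gpx4 (138 ± 42.4 to 599 ± 54.3 CPM). With an estimated correlation the camera adjusted p of these 4 lists was 0.792. Lipogenesis genes went both ways (10 rose and 6 fell of 30, camera adjusted p = 0.569), with Scd2 up by 1.88 ± 0.18 and Mlxipl, the carbohydrate-responsive regulator, at -1.78 ± 0.22. Bile acid genes did too (7 rose and 11 fell of 28, camera adjusted p = 0.569), with the sterol exporter Abcg5 up by 1.53 ± 0.24 and the receptor Fgfr4 at -1.92 ± 0.17.

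Hepatocyte markers fell in 12 of 19 and rose in 1 (median -0.62, camera adjusted p = 0.0246, and 0.792 with an estimated correlation), including the transcription factor Hnf1a (38.8 ± 4.05 to 11.6 ± 3.61 CPM), Fga (6509.6 ± 1644 to 3168 ± 472 CPM) and the retinol carrier Rbp4 (2076 ± 417 to 1083 ± 229 CPM), and the list was not called without chow_WT 3 (median -0.54). Periportal genes fell in 10 of 20 and rose in 3, with Cyp2f2 and Hal at -1.73 ± 0.21 and -2.05 ± 0.27. Pericentral genes fell in 10 of 20 and rose in 2, and neither zone was called as a list (camera adjusted p = 0.196 and 0.161). Among drug metabolism genes, where 4 rose and 5 fell of 26 (median -0.11, camera direction up, adjusted p = 0.909), Cyp1a2 fell from 704 ± 158 to 182 ± 53.3 CPM. Genes of glucose and insulin signalling fell in 10 of 24 and rose in 5 (median -0.25, camera adjusted p = 0.275), with the insulin receptor Insr going from 255 ± 35.1 to 87.8 ± 9.67 CPM, Irs1 at -1.40 ± 0.17 and Foxo1 at -1.90 ± 0.26. Acute phase genes fell in 12 of 26 and rose in 6, and interferon genes fell in 6 of 33 and rose in 2 (camera adjusted p = 0.734 and 0.434).

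Mitochondrial genes changed in both directions. Nuclear genes of the respiratory chain rose in 38 of 75 and fell in 4 (median 0.37, camera adjusted p = 3.11e-04, and 0.792 with an estimated correlation), as in the complex I subunits Ndufa5 (19.3 ± 6.55 to 65.5 ± 11.1 CPM) and Ndufb3 (log2 fold change 0.93 ± 0.12 SE). Fission and fusion genes rose in 11 of 27 and fell in 5 (median 0.04, camera adjusted p = 0.465). The formin Inf2, which drives actin-dependent fission, fell from 51.2 ± 6.06 to 9.28 ± 2.85 CPM and the Drp1 receptor Mief1 from 49.2 ± 7.95 to 21.3 ± 1.80 CPM, while the crista organizer Immt rose from 91.8 ± 3.99 to 166 ± 12.8 CPM. Mitochondrial calcium genes fell in 11 of 32 and rose in 9 (median -0.11, camera adjusted p = 0.382). The calcium-regulated carrier Slc25a23 was at -2.25 ± 0.18, the sodium-calcium exchanger Slc8b1 at -1.50 ± 0.13 and the calcium release channel Itpr2 at -1.20 ± 0.11. Of the mitophagy genes 8 rose and 4 fell of 24 (camera adjusted p = 0.382), with Ulk1, which starts autophagy, at -2.94 ± 0.26 and the lysosomal protein Lamp1 at 0.75 ± 0.13. Stress genes also went both ways, with 10 up and 6 down of 25 in the integrated stress response (Ddit3 at 1.37 ± 0.19, Trib3 at -1.80 ± 0.24) and 4 up and 4 down of 22 in ER stress (Atf3 at 3.46 ± 0.34, Ern1 at -1.78 ± 0.19, Syvn1 at -2.80 ± 0.19). Neither was called as a list (camera adjusted p = 0.398 and 0.775).

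The direction of the KO effect on GAN was set against the difference between the experiments. Both contrasts use the GAN_WT libraries, so chance alone gives a negative correlation. Across 15737 genes r between GAN_KO minus GAN_WT and GAN_WT minus chow_WT was -0.39, and the covariance was -0.140. Simulated groups with no effect gave an r of -0.57 and a covariance of -0.0537. The simulated groups also held no difference between the experiments, so their r cannot be compared with the real r. With the GAN_WT libraries divided so that the contrasts shared none, r averaged -0.24 over 6 divisions (range -0.33 to -0.16). Ptprb, 245 ± 42.4 CPM in chow_WT, 92.6 ± 17.4 in GAN_WT and 157 ± 29.4 in GAN_KO, and Lyz2, 57.1 ± 19.4, 556 ± 418 and 246 ± 49.6 CPM, are examples chosen after their values were seen.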

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

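The counts over other splits of the samples were planned before the data were examined for the numbers of genes called, and chosen after for the numbers of lists called and for the length trend. For the endothelial and macrophage lists camera and leaving out each library were planned too, and the counts of splits, the lists matched on length, the length correction, the bounds for GAN_WT 1 and the comparison with stellate markers were chosen after their values were seen. The planned tests of linked alleles, time of day, sex and library size for called genes had no called genes to work on in either KO contrast.

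For the genotype contrasts the number of genes called was 0 by edgeR, and every split of the samples reaches a count of 0, so the counts of splits for it can say nothing about chance. In the chow experiment all 100 splits of the 10 libraries reached it (highest other 45, with 180 genes at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 0 by limma-voom with quality weights), in the GAN experiment all 100 (highest other 182, with 2141 at an unadjusted p under 0.05, 112 higher and 35 lower by DESeq2 and 1 by limma-voom with quality weights), and for the difference between the genotype effects all 100 relabelings (highest other 2, with 701 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom with quality weights). The numbers of genes at an unadjusted p under 0.05 can be compared, and as many were reached by 89, 5 and 38 of 100 (highest other 3401, 3248 and 3087), so chance could not be excluded for any of the 3. Most splits called 0 genes (97 of 100 in chow and 94 of 100 in GAN livers), and the few that called up to 45 and 182 point to a structure of some samples other than genotype, which was not tested. For the wild-type livers of the 2 experiments, fitted alone, 8036 genes were called, which 1 of 100 splits reached, the real one, against 4955 in the highest other, so chance is excluded there.

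Endothelial markers lay above WT in GAN_KO livers. Chance could not be excluded, since 6 of 100 splits of the 9 libraries gave a list median as large in size as 0.26 (highest other 0.34). The list was called after the length correction with a median of 0.25 (0.10 without GAN_KO 3, still called). This argues against the trend with transcript length as the whole cause. The list lay at the 99.95 percentile of lists matched on length and expression, whose median was 0.05. Those lists were drawn gene by gene, so the percentile leaves out that endothelial genes vary together and cannot exclude the trend by itself. Within the list, across genes, the fold change before the correction followed length (rho = 0.69). A higher share of endothelial RNA in GAN_KO livers stays open as a hypothesis, as does a structure of the samples unrelated to genotype.

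Macrophage markers lay below WT in GAN_KO livers. Chance could not be excluded, since 11 of 100 splits gave a list median as large in size as 0.71 (highest other 0.78). After the length correction stellate cell markers had a median of -0.062 and endothelial markers 0.25, so they did not fall as the macrophage markers did. The distances from the macrophage markers were 3.53 and 4.96 standard errors over genes. These errors treat the genes of a list as independent and leave out the spread between livers. A lower share of all cells other than hepatocytes is therefore not excluded. Without GAN_WT 1 the median was -0.36, between the bounds set for and against that liver as the whole cause, so its part in the pattern is undecided. Fewer macrophages in the KO livers, or more in GAN_WT 1 for reasons unrelated to genotype, remain open as hypotheses.

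Of 164 groups of values examined, 9 had a sample that stood apart from the rest of its group. About 1 in 20 groups does so by chance. The chow_WT 3 library had counts for 19718 genes against 21093 to 21459 in the other chow_WT libraries, and GAN_KO 5 had 12.4% of its counts on mitochondrially encoded genes against 8.82 to 9.70% in the other GAN_KO libraries. Among list levels on the log2 scale, chow_KO 5 stood apart for macrophage markers (-0.44, others 0.01 to 0.08) and for fission and fusion genes (0.12, others -0.05 to -0.01). The level of ER stress genes in chow_KO 3 was 0.57 (others -0.16 to 0.02). In chow_WT 4 the periportal level was -0.33 (others 0.05 to 0.10) and the lipid droplet level -0.16 (others 0.03 to 0.10). The pericentral level of GAN_WT 4 was 0.29 (others -0.14 to -0.07) and the blood level of GAN_KO 4 was 0.45 (others -0.24 to -0.07).

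By camera the genotype effect differed between the experiments in 14 lists of pathways or cell types, though the chow groups also differed in sex. It was lower on the GAN diet for macrophages (camera adjusted p = 1.58e-04), T and NK cells (0.0188), B cells (0.00912), neutrophils (0.00265), the nuclear respiratory chain (0.00265), mitophagy (0.0234), the integrated stress response (0.0373), ER stress (1.47e-05) and antioxidant genes (0.0470). It was higher for matrix genes (0.0188), the endothelium (7.99e-05), mitochondrially encoded genes (0.0188), the cell cycle (0.00535) and interferon genes (1.47e-05). Male-biased liver genes, a covariate list, also had a lower effect on the GAN diet (camera adjusted p = 1.51e-04). The adjusted p was 0.876 with an estimated correlation for each of these lists, and 51 of 100 relabelings called at least the 15 lists of the real labels (highest other 29), so chance could not be excluded for their number. The same holds within the experiments, where 32 of 100 splits of the chow libraries called at least the 17 lists of the genotypes (highest other 24) and 71 of 100 GAN splits at least 13 (highest other 29). It holds also for the trend of GAN fold changes with transcript length, since 9 of 100 splits gave a rho as large in size as 0.437 (highest other 0.503). In further counts that were not planned, a GAN list median as large in size came from 30 of 100 splits for the respiratory chain, 48 for cytokines and 51 for interferon genes. It came from 8 for T and NK cells, 7 for the acute phase and 3 for ER stress. The GAN ER stress count is 1 of several and was not adjusted for their number. For chow list medians the counts were 37 of 100 for interferon genes, 30 for the acute phase and 73 for ER stress. With 1 library left out at a time, the lists called each time were ER stress, the endothelium, interferon and male-biased genes, 4 of the 15. For the others the library that raised the camera adjusted p most was GAN_WT 1 for macrophages (0.123), T and NK cells (0.417), B cells (0.209) and neutrophils (0.0765), GAN_WT 4 for matrix (0.633), chow_WT 2 for the cell cycle (0.336), chow_WT 3 for mitochondrially encoded genes (0.157), chow_WT 4 for the respiratory chain (0.397) and for antioxidant genes (median -0.07 without it), chow_KO 3 for the integrated stress response (0.216) and GAN_WT 4 for mitophagy (0.109). Over all libraries left out the median ran from 0.10 to 0.28 for matrix, -0.83 to -0.08 for T and NK cells, -0.84 to -0.18 for B cells, -0.19 to 0.0089 for the respiratory chain, -0.27 to -0.09 for the integrated stress response and -0.17 to -0.06 for antioxidant genes.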

How the results depend on the processing

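Male livers alone (with each of them left out in turn), a sex term, leaving out chow_KO 3 with chow_WT 3, the length correction and the unadjusted threshold near Efhd1 were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the labels give no numbers that pair livers.

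In chow livers DESeq2 called 1 gene higher (Gm24305, a small nuclear RNA) and 1 lower (Col1a1). Gm24305 had 5469 counts in chow_KO 2 and 4094 in chow_KO 5. The other chow_KO libraries held 13 to 33 counts and the chow_WT libraries 18 to 30, so chow_KO 2 and chow_KO 5 alone carried the difference. Leaving out 1 library gave 0 to 1 higher in edgeR, the 1 being Rhbdd1 without chow_WT 2. In GAN livers DESeq2 called 112 higher and 35 lower, edgeR without a filter 41 and 5, and edgeR with 1 surrogate variable 12 and 6. Genes called higher there had long transcripts, with medians of 7034.5, 7351 and 7911 bases against 3414, 2277 and 3207 in all genes tested, and 36 of the 41 and 6 of the 12 were also called by DESeq2. Limma-voom with quality weights, and an adjusted p under 0.1 in edgeR, each called 1 gene higher in GAN livers, Gm47283. For the difference between the genotype effects 1 gene, Rhbdd1, was lower with limma-voom with quality weights, in male livers alone and without chow_WT 2.

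The number of lists called by camera fell to 0 with an estimated correlation in all 4 comparisons, and fry called 0 in the 3 with genotype and 27 between the experiments. Leaving out 1 library gave 9 (without chow_KO 5) to 21 (without chow_WT 5) chow lists, with 11 without chow_KO 3 or chow_WT 4, against 17.

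Single genes whose log2 fold change reversed did not pass the threshold before or after. They were Dcn 0.021, Hmgcs2 -0.013 and Iigp1 0.029 with limma-voom with quality weights, Calr -0.10 and Iigp1 0.077 without chow_KO 3 and chow_WT 3, and Dcn 0.058 and Bst2 0.022 in male livers. Leaving out 1 chow library moved Hspd1 from -0.034 to 0.11, Calr from -0.090 to 0.16, Hsp90b1 from -0.00281 to 0.11, Hmgcs2 from -0.073 to 0.17, Fga from -0.26 to 0.010 and the drug metabolism list median from -0.10 to 0.25. Leaving out 1 GAN library moved Hsp90b1 from -0.10 to 0.010 and Rhbdd1 from -0.080 to 0.013. Of the 17 list medians that changed sign in male chow livers, 5 belonged to lists called with all livers, none of them past the threshold in males. These were matrix 0.046, cell cycle 0.11, antigen presentation 0.19, histones 0.18 and lipid-associated macrophages 0.028. Another 7 were called in males alone, among them the respiratory chain at 0.23 (from -0.08) and macrophages at 0.18 (from -0.15). For the difference between effects the median of mitochondrially encoded genes fell in male livers from 0.29 to 0.037, where camera placed the list lower. After the length correction leaving out 1 GAN library moved the periportal median from -0.039 to 0.22 and the cell cycle median from -0.070 to 0.25. The cause was not tested. The r of the reversal was -0.226, -0.249, -0.297, -0.163 and -0.159 in the other 5 divisions of the GAN_WT libraries. Near Efhd1 the share of genes past the threshold, below that of all genes tested within 20 Mb in both KO contrasts, lay above it within 10 Mb (2 chow and 16 GAN genes), and between the experiments it lay below on chromosome 1 (595 genes).

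Values of named genes kept their direction and side of the threshold in 489 chow, 714 GAN, 213 difference and 1833 experiment comparisons, and passed the threshold only under an alternative in 2, 22, 3 and 0. Lists kept both in 130, 107, 235 and 340 and lost the call in 103, 49, 94 and 34. Depth limits Efhd1, at 0 to 8 counts per library.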

Other observations

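The comparisons in male livers, the tests of linked alleles and of sex for Rhbdd1, the relabelings of the reversal and the look at Gm47283 were chosen only after their values were seen.

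In the 7 male chow livers (4 KO and 3 WT) camera called 20 lists. Nuclear genes of the respiratory chain were above WT in 74 of 75 members (median 0.23, camera adjusted p = 9.48e-19), where all 10 livers gave a median of -0.08. Fatty acid oxidation genes were above WT in 37 of 40 (median 0.30, camera adjusted p = 1.23e-09), drug metabolism genes in 22 of 24 (median 0.43, camera adjusted p = 6.72e-06), antioxidant genes in 25 of 29 (median 0.25, camera adjusted p = 6.72e-06) and ER stress genes in 21 of 22 (median 0.20, camera adjusted p = 3.24e-04). Lipogenesis (14 of 30, camera adjusted p = 0.837), lipid droplet (16 of 22, camera adjusted p = 0.226) and fission and fusion genes (19 of 27, camera adjusted p = 0.0711) were not called. With an estimated correlation the camera adjusted p of the 5 lists was 0.609, and fry gave 0.639. Cell type and covariate lists were called too. Among them hepatocyte markers (median 0.22, camera adjusted p = 0.00294), pericentral genes (0.19, 0.00143) and immediate early genes (17 of 18, 0.31, 0.0105) were higher. Bile duct markers were lower (median -0.65, camera adjusted p = 0.00165). With 1 liver left out at a time, the medians were lower without chow_WT 4 for fatty acid oxidation (0.18) and drug metabolism (0.26, camera adjusted p = 0.0256), and the respiratory chain median was 0.16 without it and 0.15 without chow_KO 3. Without chow_KO 3 ER stress genes were not called (median 0.06, camera adjusted p = 0.0604), their median was 0.31 without chow_KO 4, and that of drug metabolism was 0.70 without chow_WT 5. Among the 35 splits of the 7 libraries, 1, the real one, gave a respiratory chain median as large as 0.23 (highest other 0.22), but the list was picked for its value, so this count says nothing about chance. Over all lists, 7 of the 35 splits gave a smallest camera p as small as the real one (-log10 p of 19.7, highest other 26.2), and 6 called as many as 20 lists (highest other 24), so chance could not be excluded. The library of chow_KO 3, 1 of the 4 male KO livers, had low Malat1 (892 CPM, others of its group 2545 to 6675).

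Rhbdd1, a protease of the rhomboid family that lies 4.91 Mb from Efhd1 in GRCm38, measured 21.5 to 29.3 CPM in the 5 chow_KO livers and 10.1 to 21.2 CPM in the 5 chow_WT livers (log2 fold change 0.88 ± 0.20 SE, edgeR adjusted p = 1.00). The highest WT liver, chow_WT 2, lay below all 5 KO livers with the chow libraries scaled alone, but at 21.46 CPM above chow_KO 1 with all 19 libraries scaled together, and without it the log2 fold change was 1.13 (edgeR adjusted p = 0.0272, against 0.0874 to 1.00 under the other alternatives). The GAN log2 fold change was -0.024 (95% interval -0.205 to 0.157). This argues against an allele linked to the Efhd1 locus that separates KO from WT and acts alike in both experiments. The chow log2 fold change was 1.13 in male livers alone (edgeR adjusted p = 0.145), which argues against sex as the source. Chance was not tested for this gene, which was picked after its values were seen, and it stays open. An allele that varies among the chow WT mice also stays open as a hypothesis.

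The KO effect on GAN was set against the difference between the experiments and compared with relabeled genotypes. With GAN_WT libraries divided so that no library was shared, the mean r across genes of -0.237 was reached by 3 of 100 relabelings, the real one included (lowest other -0.269). After the length correction it was -0.195, reached by 5 of 100 (lowest other -0.255). Both counts are among several that were not planned and were not adjusted for their number, so chance could not be excluded for either.

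Gm47283, annotated on the Y chromosome in GRCm38, had 0 counts in all 4 GAN_WT livers and 12 to 24 counts in the 5 GAN_KO livers. In chow livers it was at 0 in 1 KO library (chow_KO 3, male) and 1 WT library (chow_WT 2, female). It reached 6.91 CPM in KO and 11.7 CPM in WT. The female livers chow_KO 1 and chow_WT 3 measured 5.38 and 2.65 CPM, which argues against the Y chromosome as the only source of its chow reads.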
